A study of Mus musculus with 16 samples.

How the data were processed

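Gene expression was measured in whole gonads of mouse embryos on Agilent arrays with a single Cy3 label. Per the labels, gonads were dissected in cold buffer and stored frozen, total RNA was extracted, and 0.2 µg of it was amplified and labelled. The 16 samples are female or male, heterozygous (Nanos3+/-) or knockout (Nanos3-/-), and from embryonic day (E) 12.5, 13.5, 14.5 or 15.5, with 1 sample for each combination. By its title, each sample holds replicates 1 and 2 combined, and the separate replicates were not analysed here.

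The deposited values are linear ratios: each probe's signal on an array, divided by that probe's typical signal over the samples. The labels name Agilent Feature Extraction 9.5, and do not say how the authors scaled the arrays, centred the probes or combined the replicates. That each value is such a ratio was read from the values themselves. The medians of most probes lie close to 1, no value is negative, and the lowest is 0.01. The ratios also show that weak signals had been set to a limit before scaling, since many probes share the same ratio between any pair of samples. This limit was recovered for each sample, with a tolerance of 2e-04 (log2). In a test on 10000 simulated probes the recovered limit was off by at most 4.6e-06 (log2). Among probes at the limit in more than 1 sample, 100% of the values at the limit were found. A value at the limit in a single sample cannot be found this way. The simulation had 1 array per sample, so it did not test samples where only 1 of the 2 combined replicates was at the limit.

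Of 41267 probes in the table, 93 control probes were left out. Of the other 41174 probes, 32664 have a single gene symbol, and these cover 19532 genes. Each array was scaled to the same 75th percentile over the 28373 probes that were never at the limit, which moved arrays by -0.33 to 0.26 (log2). The recovered limits of the samples differed by up to 1.08 (log2) in the deposited values. All values of a probe were therefore raised to the highest of its 16 sample limits, so that every sample has a common limit, and log2 was taken. The plan made before the data were examined assumed signal intensities or log2 values, a floor at a percentile and a filter on the array median. Values centred per probe do not allow that filter, so genes above the limit in at least 4 of the 16 samples were kept instead. For a gene with several probes, the probe at the limit in the fewest samples was used, and among equals the probe with the highest mean, where the plan had named the highest mean alone. That mean is of ratios centred per probe, so it does not rank probes by signal. The filter and the probe choice left 16581 genes. Among genes with several probes that were called and changed at least 2-fold, the probes differed in sign for 67 of 443 genes in the female knockout comparison and for 64 of 288 in the male one.

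Models were fitted with limma 3.58.1 (lmFit and eBayes with a trend of the variance on the mean log2 ratio) in R 4.3.3, on all 16 samples together. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 16581 genes. The knockout effects and their difference between the sexes were fitted with a term for each combination of sex and day. The sex effects were fitted with a term for each combination of genotype and day. Both models leave 6 residual degrees of freedom. Slopes per day were fitted in each group with 8 residual degrees of freedom, and the change of the knockout effect per day with 4. All p-values therefore rest on the 4 embryonic days. For the knockout and sex effects the days are the replicates, and real changes of an effect between days count as error. For the slopes, departures from a straight line count as error. The pairing by day was checked on the deviation of each sample from the mean of its group. Correlations of these deviations across genes ran from 0.478 to 0.758 between the heterozygous and knockout samples of a sex and day. Between the male and female samples of a genotype and day they ran from 0.187 to 0.641. In 8 of 8 pairs of the first kind and 6 of 8 of the second the correlation was above those with the other days of the partner group, and the exceptions were both pairs of E12.5. Deviations within a group cancel out, which lowers correlations with the other days and so favours the same day. Errors given with ± are standard errors from limma unless named otherwise. Arrays give no counts, so the number of arrays limits the precision. A fold against a group whose samples are all at the limit is given as a lower bound. Where only some samples of a group are at the limit, the fitted difference is given and may be larger in size, as for Dmrt1 and Rhox13 in female knockouts, Mael and Xist in male knockouts and Nanos2 in female heterozygotes.

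Gene lists fixed before the data were examined cover pluripotency-associated and early germ cell genes, pan-germline genes, meiosis, male germ cell and oocyte genes, and Sertoli cell, pre-granulosa, fetal Leydig cell, adrenocortical, and interstitial and peritubular genes. Further lists cover WNT response, endothelial, macrophage, erythroid, mesonephric, retinoic acid, cell cycle, p53 response, immediate early and heat shock, housekeeping and Y-linked genes, with Nanos3 and Xist on their own. Lists of 3 or more measured genes were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Lists of hepatocyte, embryonic globin, erythroid progenitor, and megakaryocyte and granulocyte genes were written after the data were examined, for the closing section. Of their 21, 3, 11 and 16 measured genes, 1, 3, 6 and 0 are also on a list fixed before. Ratios centred per probe do not show which genes of a list are the most abundant. The genes named in the text follow a rule fixed before the data were examined. It takes Nanos3, Xist and the Y-linked genes, and for each comparison the 8 highest and 8 lowest called genes of the same sign on all 4 days. It adds up to 4 members of each list with the smallest p, and 15 fixed genes: Pou5f1, Ddx4, Dazl, Stra8, Sycp3, Nanos2, Dnmt3l, Sox9, Amh, Foxl2, Wnt4, Fst, Cyp11a1, Insl3 and Cyp26b1. Insl3 was not among the genes tested.

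The fit was tested on simulated data, with 200 of the 16581 genes changed. In the female knockout comparison 35.8%, 67.2% and 89.4% of changes of 1.5, 2 and 4-fold were found, with 5 false calls. In the comparison of the knockout effect between the sexes these shares were 4.48%, 32.8% and 87.9%. Alternatives to the normalization, filter, probe choice, array weights, variance model, day block and samples were run, each embryonic day was left out in turn, and further scalings and filters were added after the data were examined. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.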

Results

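Expression was measured in 16 samples of mouse embryonic gonad, in 4 groups of 4: female heterozygous, female knockout, male heterozygous and male knockout for Nanos3. Nanos3 encodes an RNA-binding protein that primordial germ cells need to survive. Each group holds 1 sample from each of E12.5, E13.5, E14.5 and E15.5, and each sample combines replicates 1 and 2, so the days serve as replicates (n = 4 per group). Of 41174 probes, between 1554 and 11174 per sample were at the detection limit, and 16581 genes were tested. Differences are log2 values, knockout minus heterozygous or male minus female, ± standard error from limma with n = 4 pairs of samples unless stated otherwise. The spread behind a standard error is estimated for each gene over all groups of the model together. Both sexes, or both genotypes, therefore share 1 standard error per gene, which does not show the spread of the 4 pairs alone.

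Xist, the RNA that silences the second X chromosome of female cells, was lower in male than in female gonads, at -7.67 ± 0.89 in heterozygotes and -8.37 ± 0.89 in knockouts. All 3 measured Y-linked genes were higher in males in both genotypes (3 of 3 adjusted over the list alone), and Kdm5d was at least 45.8-fold higher in heterozygous males. The sex in the sample titles therefore matched these genes in all 16 samples, although the description of every female sample names male gonads. In males, Nanos3 itself was lower in knockouts (-2.55 ± 0.41, adjusted p = 0.00363, lower on 4 of 4 days). In females the difference was -0.23 ± 0.41 (adjusted p = 0.709), with -1.52 at E12.5 and 0.52 at E15.5. The difference of the Nanos3 effect between the sexes did not pass the test (-2.33 ± 0.58, adjusted p = 0.104). It was called in 2 of 14 other settings, over which it ran from -3.03 to -1.90. Whether the Nanos3 probe lies in the deleted part of the gene is not known, and if it lies outside, its level does not check the genotype.

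The comparison of female knockout with female heterozygous gonads asks which genes depend on germ cells in the fetal ovary. The median difference of pan-germline genes by day ran from -5.56 to -5.11 and that of meiosis genes from -7.43 to -3.89. Of 23 pan-germline genes 22 were lower (22 adjusted over the list alone, median -5.04), among them Ddx4, which encodes a germ cell RNA helicase (-7.75 ± 0.45, adjusted p = 3.56e-05), Dazl (-6.94 ± 0.45) and the piRNA pathway gene Mael (-8.82 ± 0.63). Of 24 meiosis genes 23 were lower (24 adjusted over the list alone, median -5.61), including the meiotic cohesin gene Smc1b (-9.02 ± 0.47, 521-fold), the synaptonemal complex gene Sycp3 (-8.16 ± 0.43) and Stra8, which marks entry into meiosis (-8.80 ± 1.13). Asz1 was at the detection limit in all 4 knockout samples and at least 117-fold lower.

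Of the 16 pluripotency-associated and early germ cell genes, 9 were lower in female knockouts (12 adjusted over the list alone, median -1.86), including Pou5f1 (-4.27 ± 0.97), Dppa3 (-4.46 ± 0.92) and Zfp42 (-4.65 ± 0.37). Of 9 oocyte genes 3 were lower (3 adjusted over the list alone). These were the oocyte transcription factor genes Figla and Lhx8, at the limit in all 4 knockout samples and at least 95.3-fold and 20.6-fold lower, and Nobox (-4.00 ± 0.53). Of 7 male germ cell genes 1 was lower (1 adjusted over the list alone), Rhox13 (-8.75 ± 0.61, a bound, since 3 of the 4 knockout samples were at the limit). Camera called the pan-germline (adjusted p = 9.54e-21), meiosis (4.10e-22), pluripotency (1.55e-06) and oocyte lists (0.0382). None of these calls held with an estimated correlation, which gave adjusted p = 0.100 for pan-germline, 0.155 for meiosis and 0.441 for pluripotency and for oocyte genes.

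**Figure D1:**
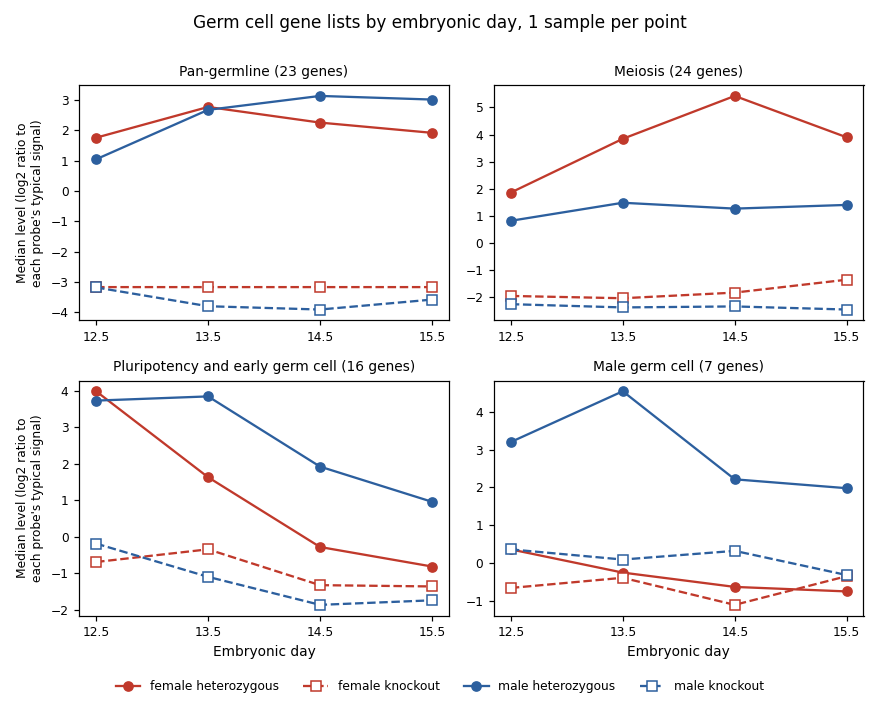
Median level of 4 germ cell gene lists (log2 ratio to each probe's typical signal) against embryonic day, with 1 point per sample, filled circles for heterozygous and open squares for knockout gonads, red for female and blue for male. The pan-germline median of the female knockout samples sits at -3.17 on every day, which is the detection limit of the gene at the median, while the female heterozygous samples lie between 1.76 and 2.77.

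In female knockouts the medians of the pre-granulosa, Sertoli and Leydig lists moved far less than those of pan-germline and meiosis genes. Most called members of these somatic lists were higher with the scaling used here. Of 15 pre-granulosa genes 6 were higher (6 adjusted over the list alone, median 0.47), including Wnt4, a signal of ovarian development (0.70 ± 0.13), the KIT ligand gene Kitl (0.70 ± 0.13) and Nr0b1 (0.92 ± 0.10). Foxl2, a transcription factor that maintains granulosa cell identity, differed by 0.04 ± 0.15 (95% interval -0.31 to 0.39, adjusted p = 0.860), and the activin antagonist gene Fst by 0.39 ± 0.35 (adjusted p = 0.419). Of 23 Sertoli cell genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone). Sox9, which drives testis development, was 1.86-fold higher (0.90 ± 0.10, adjusted p = 0.00073, higher on 4 of 4 days), and the lower gene was Dmrt1, which germ cells also express (-2.40 ± 0.49). Amh differed by 0.17 ± 0.34 (adjusted p = 0.740), and the Sox9 level in female knockouts stayed 2.52 below that of male knockouts. Over 15 other settings the difference ran from 0.04 to 0.96 for Amh and from 0.27 to 0.95 for Fst, without a call. Of 10 fetal Leydig cell genes 4 were higher (4 adjusted over the list alone), including the steroid enzyme genes Hsd3b1 (1.32 ± 0.14) and Cyp11a1 (0.96 ± 0.21).

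Of 9 WNT response genes 4 were higher in female knockouts (6 adjusted over the list alone), including Rnf43 (0.92 ± 0.14) and Sp5 (0.65 ± 0.21). Higher members were also found among interstitial and peritubular genes (4 of 11, with the hedgehog target Hhip at 1.44 ± 0.18), endothelial genes (5 of 14), macrophage genes (4 of 14) and retinoic acid genes (4 of 12). Adjusted over the list alone these counts were 4, 5, 4 and 5. Of 10 erythroid genes 9 were higher (10 adjusted over the list alone, median 1.72), including the erythroid transcription factor gene Klf1 (3.43 ± 0.61) and the Rh-associated glycoprotein gene Rhag (2.98 ± 0.51). Other genes of blood cells were among the largest increases, such as Hemgn (3.96 ± 0.79) and Prg2 (3.73, SD 3.23 over n = 4 days, with 8.43 at E14.5), beside Apol8 (4.31 ± 0.61). Camera called the pre-granulosa list (adjusted p = 0.0221) and the erythroid list (adjusted p = 9.06e-05). Both had adjusted p = 0.331 with an estimated correlation.

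In the remaining female lists, 2 of 10 p53 response genes were higher and 2 lower (2 and 2 adjusted over the list alone), the lower ones being Pmaip1 (-1.83 ± 0.57) and Mdm2 (-0.73 ± 0.17). Of 13 immediate early and heat shock genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone). Of 14 cell cycle genes 2 were lower and of 8 mesonephric genes 2 were higher (0 and 0 adjusted over the list alone). Of 10 housekeeping genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone), with Gapdh at 0.63 ± 0.11 and Tbp at -0.58 ± 0.10. Of the 2 adrenocortical genes 1 was higher (1 adjusted over the list alone).

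In all, 1306 genes changed at least 2-fold in female knockouts, 293 of them higher and 1013 lower, among 5610 called genes of any size (3465 higher, 2145 lower). The median of all genes was +0.11 and the somatic values above include this shift; with the arrays scaled as deposited, 2296 genes were called, 79.1% of them lower. With no block for day 1144 genes were called (842 at least 2-fold), without E13.5 1551 (767), without E14.5 1850 (776), and with only the female samples 3588. With quantile normalization the differences grew to 1.54 for Cyp11a1, 1.46 for Rnf43, 1.10 for Kitl and 1.08 for Sp5. With the mean of all probes of a gene they were 0.51 for Cyp11a1 and 2.82 for Apol8, and without E14.5 Prg2 was at 2.16. The calls for Cyp11a1, Dmrt1, Dppa3, Figla, Gapdh, Hemgn, Kitl, Pmaip1, Pou5f1, Prg2, Rnf43, Sp5 and Wnt4 ended under at least 1 alternative that kept all days and the block.

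The same comparison in males asks which genes depend on germ cells in the fetal testis. All 23 pan-germline genes were lower in the knockout (23 adjusted over the list alone, median -5.94), including Ddx4 (-7.21 ± 0.45, adjusted p = 6.26e-05), Mael (-9.71 ± 0.63) and the piRNA pathway gene Gtsf1 (-10.04 ± 1.13). Of 16 pluripotency-associated and early germ cell genes 13 were lower (13 adjusted over the list alone, median -4.02), with Pou5f1 at -7.60 ± 0.97 and Dppa4 at -8.76 ± 0.96. Of 7 male germ cell genes 6 were lower (6 adjusted over the list alone, median -3.65). Nanos2, which directs the male fate of germ cells, was at the limit in all 4 knockout samples and at least 40.6-fold lower, Nodal was lower (-2.78 ± 0.41), and so was Dnmt3l, a cofactor of DNA methylation in male germ cells (-5.01 ± 1.28).

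Of 24 meiosis genes 18 were lower in male knockouts (18 adjusted over the list alone, median -3.23), with Stra8 at -7.23 ± 1.13 and Sycp3 at -5.79 ± 0.43, and of 9 oocyte genes 5 were lower (1 higher and 6 lower adjusted over the list alone). Egr4, outside the lists, was also lower (-9.37 ± 0.73). Camera called the pan-germline (adjusted p = 1.09e-23), pluripotency (1.42e-10), male germ cell (0.00011), meiosis (6.46e-14) and oocyte lists (0.00186). None was called with an estimated correlation, at adjusted p = 0.0652 for pan-germline and male germ cell genes, 0.222 for pluripotency and oocyte genes, and 0.199 for meiosis genes.

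In male knockouts the called members of the Sertoli, Leydig and pre-granulosa lists were higher with the scaling used here. Of 23 Sertoli cell genes 8 were higher (8 adjusted over the list alone, median 0.55), including Sox9 (0.63 ± 0.10), Inhbb (0.55 ± 0.10) and Cyp26b1, which degrades retinoic acid (0.65 ± 0.13). Amh differed by 0.83 ± 0.34 (adjusted p = 0.0880), and it was called in 4 of 15 other settings, where the difference ran from 0.71 to 1.43 over all 15. Of 10 fetal Leydig cell genes 7 were higher (10 adjusted over the list alone, median 0.71), including Cyp11a1 (0.79 ± 0.21), Hsd3b1 (0.74 ± 0.14) and the lipoprotein receptor gene Scarb1 (0.72 ± 0.15). Of 15 pre-granulosa genes 5 were higher (6 adjusted over the list alone), with Wnt4 at 0.62 ± 0.13, while Foxl2 differed by 0.22 ± 0.15 (adjusted p = 0.288). Endothelial genes (8 of 14, with Emcn at 0.53 ± 0.08 and Eng at 0.56 ± 0.08), macrophage genes (6 of 14), interstitial and peritubular genes (5 of 11) and retinoic acid genes (7 of 12) also had higher members. Adjusted over the list alone these counts were 11, 9, 6 and 7.

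Camera called the Sertoli (adjusted p = 0.0133), Leydig (0.00186), pre-granulosa (0.0275), endothelial (0.00418), macrophage (0.0237) and interstitial lists (0.0175) in males. With an estimated correlation none was called, at adjusted p = 0.212 for Sertoli, 0.199 for Leydig, 0.222 for pre-granulosa and endothelial, 0.407 for macrophage and 0.354 for interstitial genes. Of 9 WNT response genes 2 were higher and 2 lower (3 and 2 adjusted over the list alone), with Rnf43 at 0.78 ± 0.14 and Sp5 at -1.13 ± 0.21. Of 10 p53 response genes 1 was higher and 4 were lower (1 and 4 adjusted over the list alone), including the BH3-only gene Pmaip1 (-4.42 ± 0.57) and Mdm2 (2.04-fold lower). Of 10 erythroid genes 1 was higher (1 adjusted over the list alone), Alas2 (0.69 ± 0.17), and the list median was 0.68. Immediate early and heat shock genes (6 of 13 higher), mesonephric genes (3 higher, 1 lower of 8), housekeeping genes (3 higher, 1 lower of 10) and adrenocortical genes (1 of 2 higher) had the same counts adjusted over the list alone. Of 14 cell cycle genes 0 were called by limma, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05.

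In males 1120 genes changed at least 2-fold, 69 of them higher and 1051 lower, among 5686 called genes of any size (3598 higher, 2088 lower). The few increases of at least 2-fold included Nepn (4.01-fold), Fabp1 (1.78 ± 0.34) and Serpind1 (1.72 ± 0.31). The median of all genes was +0.12; with the arrays scaled as deposited 1943 genes were called, 83.1% of them lower. With no block for day 1037 genes were called, without E13.5 2204 (673 at least 2-fold) and without E14.5 1568 (625). With quantile normalization the differences grew to 2.31 for Cyp11a1, 1.79 for Hsd3b1, 1.48 for Scarb1, 1.17 for Cyp26b1, 1.02 for Sox9 and 0.84 for Inhbb, while Sp5 was at -0.35. With the mean of all probes of a gene Rnf43 was at 0.39. The calls for Alas2, Cyp11a1, Cyp26b1, Dnmt3l, Emcn, Eng, Hsd3b1, Inhbb, Rnf43, Scarb1, Sox9, Sp5 and Wnt4 ended under at least 1 alternative that kept all days and the block.

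The knockout effects of the sexes had much in common: 922 genes were lower in both sexes and 2195 higher in both, against 34 called in opposite directions. Independent calls would give 270 and 752. Both effects share the scaling and the variance estimate of each gene, so their calls are not independent. These chance counts therefore do not test the overlap, and the share of higher calls depends on the scaling. Across all genes, which are not independent replicates, the effects correlated with Pearson's r = 0.679. The test of the difference called 145 genes, 69 with a more positive and 76 with a more negative effect in males. Of 24 meiosis genes 3 had a more positive effect in males (10 adjusted over the list alone), including Meioc (4.22 ± 0.56) and the telomere attachment gene Majin (4.78 ± 0.73), and M1ap, which acts in meiosis, was higher by 4.46 ± 0.78. More negative in males were the piRNA gene Tdrd5 (-4.79 ± 0.65), Ucma (-5.31 ± 0.64) and the WNT response gene Sp5 (-1.78 ± 0.29, adjusted p = 0.0365). The calls for M1ap, Majin, Meioc, Sp5 and Tdrd5 ended under at least 1 alternative that kept all days, and that for Ucma with a day left out.

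Of 23 Sertoli cell and 15 pre-granulosa genes limma called 0 for a difference of the knockout effect between the sexes (0 and 0 adjusted over the list alone), with 3 and 1 at an unadjusted p under 0.05. The 95% intervals of that difference were -0.58 to 0.05 for Sox9, -0.31 to 0.67 for Foxl2, -0.51 to 0.35 for Wnt4, -1.17 to 1.05 for Fst and -0.42 to 1.75 for Amh. For erythroid genes the median difference was -1.05, with 0 called by limma and 7 at an unadjusted p under 0.05 (0 adjusted over the list alone). Camera called this erythroid difference (adjusted p = 0.00037; adjusted p = 0.442 with an estimated correlation) and likewise the meiosis list (adjusted p = 3.60e-08; 0.442 with an estimated correlation). The count of 145 depended on the days used: it was 1123 without E12.5, 1 without E13.5, 0 by limma without E14.5 (1374 at an unadjusted p under 0.05) and 9 without E15.5. It was 41 with no block for day, 44 with no filter, 72 with the arrays as deposited, 82 with no common limit and 892 with array weights.

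**Figure D2:**
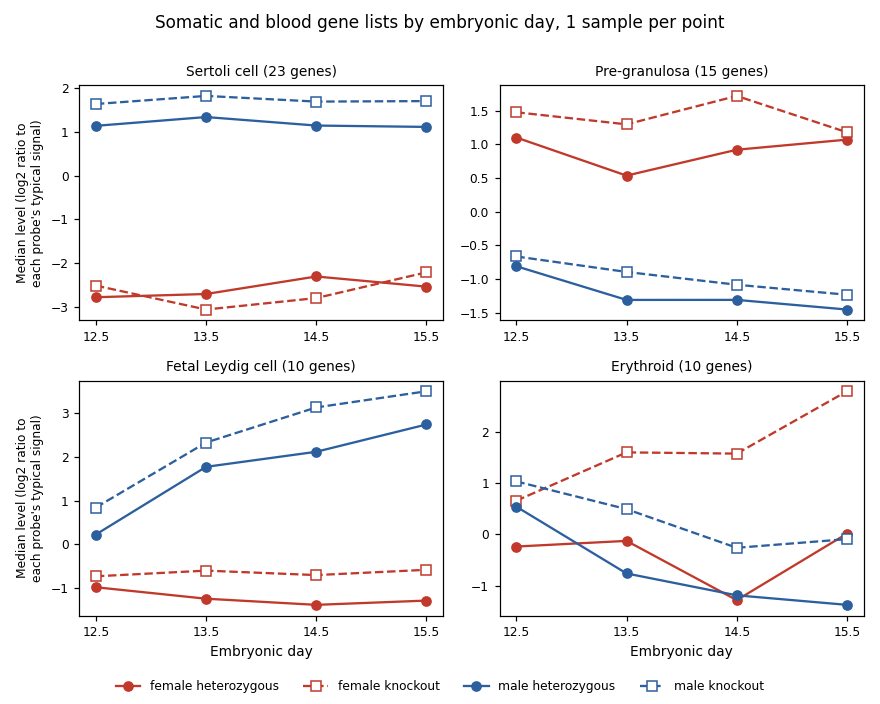
Median level of the Sertoli cell, pre-granulosa, fetal Leydig cell and erythroid lists (log2 ratio to each probe's typical signal) against embryonic day, with 1 point per sample, filled circles for heterozygous and open squares for knockout gonads, red for female and blue for male. The Sertoli cell median of the male samples lies between 1.11 and 1.82 and that of the female samples between -3.06 and -2.21, in both genotypes.

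Comparing males with females within a genotype asks whether the gonads differ by sex in heterozygotes and in knockouts. They did in both: 19 of 23 Sertoli cell genes were higher in males among heterozygotes (median 4.30) and 19 among knockouts (median 4.92), and 11 of 15 pre-granulosa genes were lower in males in each genotype (medians -2.66 and -2.60). Adjusted over the list alone these counts were 20, 22, 11 and 12. Sox9 was higher in males by 2.78 ± 0.20 in heterozygotes and 2.52 ± 0.20 in knockouts, Amh by 6.36 ± 0.48 and 7.03 ± 0.48, and Cyp26b1 by 4.72 ± 0.24 and 5.45 ± 0.24. Foxl2 was lower in males, at -2.02 ± 0.46 and -1.84 ± 0.46, as were Fst, at -6.38 ± 0.44 and -6.44 ± 0.44, and Wnt4, at -1.55 ± 0.26 and -1.63 ± 0.26. These somatic list calls held with an estimated correlation, at adjusted p = 0.00132 and 0.00082 for Sertoli cell genes and 0.00612 and 0.00349 for pre-granulosa genes.

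Other somatic lists differed by sex in both genotypes. Of 10 fetal Leydig cell genes 8 were higher and 1 lower in males in each genotype (8 and 1 adjusted over the list alone), with Cyp11a1 at 8.29 ± 1.51 in heterozygotes and 8.12 ± 1.51 in knockouts. The Leydig list had adjusted p = 0.198 and 0.166 with an estimated correlation. Of 9 WNT response genes 6 were lower in males in each genotype, with 2 higher in heterozygotes and 1 in knockouts (the same counts adjusted over the list alone). Rnf43 was lower, at -3.08 ± 0.22 and -3.22 ± 0.22 (-1.60 and -1.91 with the mean of all its probes). With an estimated correlation the WNT list had adjusted p = 0.0786 in heterozygotes and 0.0333 in knockouts. Interstitial and peritubular genes (6 and 7 of 11 higher, adjusted p = 0.0482 and 0.0201 with an estimated correlation) and mesonephric genes (5 and 5 of 8 lower, adjusted p = 0.0573 and 0.0423 with an estimated correlation) also differed. Adjusted over the list alone these counts were 8, 9, 5 and 5.

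Germ cell genes also differed by sex. Of 24 meiosis genes 23 were lower in heterozygous males (23 adjusted over the list alone, median -2.47) and 4 in knockout males (4 adjusted over the list alone, median -0.17). The meiosis list had adjusted p = 0.0786 and 0.558 with an estimated correlation. The test of this difference between the genotypes is the one above, which called 3 meiosis genes. Sycp3 was lower in heterozygous males (-2.79 ± 0.41), and in knockouts the difference was -0.42 ± 0.41 (adjusted p = 0.552). Of 7 male germ cell genes 6 were higher and 1 lower in heterozygous males (6 and 1 adjusted over the list alone), including Nanos2 (5.32 ± 0.81) and Dnmt3l (5.99 ± 1.22). In knockout males 1 was higher (1 adjusted over the list alone): Lefty2, an inhibitor of NODAL signalling, at 5.54 ± 0.66 against 6.71 ± 0.66 in heterozygotes. Of the pluripotency genes 8 of 16 were higher in heterozygous males (8 adjusted over the list alone) and 1 was lower in knockout males (0 adjusted over the list alone). For a difference of these effects between the genotypes limma called 0 of the 7 male germ cell and 0 of the 16 pluripotency genes, with 6 and 6 at an unadjusted p under 0.05 (4 and 0 adjusted over the list alone). Camera called both lists (adjusted p = 0.0107 and 0.00102; 0.442 and 0.746 with an estimated correlation). Rec8, of the meiosis list, was still lower in knockout males (-2.29 ± 0.51), and so was the pan-germline gene Taf7l, which is on the X chromosome (-5.04 ± 0.19). The calls for Sycp3 in heterozygotes and Foxl2 in knockouts ended under at least 1 alternative that kept all days.

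In all, 3949 genes differed by sex in heterozygotes (1936 higher and 2013 lower in males) and 2991 in knockouts (1491 and 1500), with 2192 and 1763 at least 2-fold. Of these, 1028 were higher in males in both genotypes, 991 lower in both and 23 opposite. Independent calls would give 174 and 182 for the first kinds. Both effects share the variance estimate of each gene, so these chance counts do not test the overlap. In heterozygotes the count was 2030 with only the samples of that genotype, 2039 without E13.5, 1452 without E14.5 (1192 at least 2-fold) and 1947 without E15.5. In knockouts it was 5444 with array weights, 1695 without E13.5, 1437 without E14.5 and 1825 without E15.5.

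**Figure D3:**
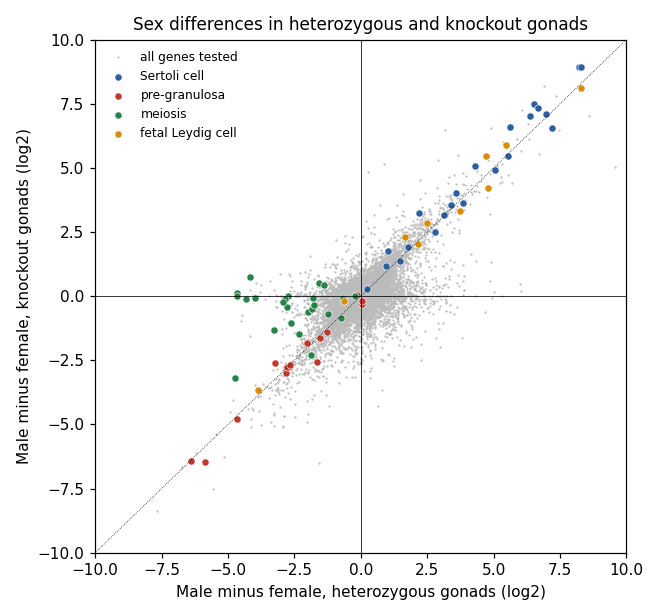
Male minus female difference (log2) of each of 16581 genes in heterozygous gonads (horizontal axis) and knockout gonads (vertical axis), with the members of 4 lists in colour and a dotted line where both differences are equal. Sertoli cell genes lie near that line, with medians of 4.30 and 4.92, while meiosis genes have medians of -2.47 on the horizontal and -0.17 on the vertical axis, where they reach down to -3.17 (Stra8).

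The slopes per embryonic day ask how each gonad changed from E12.5 to E15.5. In female heterozygotes 13 of 16 pluripotency-associated and early germ cell genes fell (15 adjusted over the list alone, median -1.62 per day), with Pou5f1 at -2.55 ± 0.29, Nanog at -2.40 ± 0.23 and Sox2 at -2.59 ± 0.32 per day. Of 24 meiosis genes 6 rose (15 rose and 1 fell adjusted over the list alone), including Sycp1 (1.60 ± 0.35) and the double-strand break gene Spo11 (1.09 ± 0.20). Of 9 oocyte genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Lhx8 rising by 1.23 ± 0.18 per day. Foxl2 rose in female heterozygotes by 0.48 ± 0.10 and in female knockouts by 0.49 ± 0.10 per day. With an estimated correlation the pluripotency list had adjusted p = 0.0506 and the meiosis list 0.830. The calls for Foxl2 and Sycp1 in female heterozygotes ended under at least 1 alternative that kept all days. Without E12.5 the slope was 0.63 for Sycp1, 0.72 for Spo11 and 0.81 for Lhx8, and without E15.5 it was 2.46 for Sycp1 and 1.69 for Spo11.

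In male heterozygotes 7 of 10 fetal Leydig cell genes rose (8 adjusted over the list alone, median 0.92 per day), and in male knockouts 7 (9 rose and 1 fell adjusted over the list alone, median 0.82). Cyp11a1 rose by 1.72 ± 0.38 and 1.71 ± 0.38 per day, and Star, which carries cholesterol into mitochondria, by 1.32 ± 0.28 and 1.42 ± 0.28. These 4 calls ended under at least 1 alternative that kept all days, and without E12.5 the slopes were 0.75 and 0.84 for Cyp11a1 and 0.68 and 0.75 for Star. With array weights the slopes in male knockouts were 0.97 and 0.84, and with quantile normalization the Star slope in heterozygotes was 0.81. The Leydig list had adjusted p = 0.320 and 0.257 with an estimated correlation. Of 23 pan-germline genes 10 rose and 3 fell in male heterozygotes (14 and 4 adjusted over the list alone; adjusted p = 0.429 for the list with an estimated correlation), including the piRNA pathway genes Tdrd1 (1.81 ± 0.25, and 1.19 without E12.5), Tdrd9 (2.44 ± 0.29) and Piwil2 (1.16 ± 0.16, and 0.64 with quantile normalization). Dnmt3l rose by 3.02 ± 0.32 per day, and Pou5f1 had a slope of -0.29 ± 0.29 (adjusted p = 0.509). Among early germ cell genes in male knockouts, slopes of -2.03 for Dppa3, -1.33 for Pou5f1 and -1.39 for Zfp42 were called. Each of these calls ended under at least 1 other setting. Whether germ cells remained in the knockouts at the early days was not tested.

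The embryonic globin gene Hbb-bh1 fell in all 4 groups, with slopes of -1.91 ± 0.12 per day in female and -2.35 ± 0.12 in male heterozygotes, and of -1.48 ± 0.12 and -2.43 ± 0.12 in female and male knockouts. In female knockouts 6 of 10 erythroid genes rose and 3 fell (7 and 3 adjusted over the list alone), with Klf1 rising by 1.68 ± 0.22 and Gata1 by 1.12 ± 0.15 per day. The mean of that list was 0.25 and its median 0.92, and camera did not call it (adjusted p = 0.0750). Stra8 rose in female knockouts by 1.95 ± 0.46 per day (adjusted p = 0.0444), from a level of -6.21 to 0.03, against levels of 3.97 to 7.55 in female heterozygotes. That call ended in 7 of 13 other settings, where the slope ran from 1.44 to 2.08 and the adjusted p up to 0.328.

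The slopes called 1620 genes in female heterozygotes (1068 rose), 2736 in male heterozygotes (1771 rose), 557 in female knockouts (386 rose) and 965 in male knockouts (546 rose). Between the genotypes, 427 genes rose and 220 fell in both male groups (58.3 and 24.4 for independent calls). In both female groups 186 rose and 74 fell (24.9 and 5.69 for independent calls). Samples of the same day deviate together and the slopes share the variance estimate of each gene. The values for independent calls therefore do not test the overlap. With a day left out the counts ran from 47 to 1289 in female heterozygotes (47 without E12.5), 261 to 2821 in male heterozygotes (261 without E15.5), 0 to 511 in female knockouts (0 by limma without E12.5) and 0 to 1126 in male knockouts (0 by limma without E15.5). At an unadjusted p under 0.05 these counts of 0 became 1994 and 1871. With array weights they were 799, 6515, 4966 and 5148, and with the arrays as deposited 3098 and 506 in female heterozygotes and male knockouts.

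Slopes of the knockout effect ask whether the difference between genotypes grew or shrank with stage. In females the knockout difference of pluripotency genes shrank: 9 of 16 had a rising effect (13 adjusted over the list alone, median 1.45 per day). The list had adjusted p = 0.280 with an estimated correlation. From E12.5 to E15.5 its median level fell from 3.98 to -0.82 in female heterozygotes and went from -0.69 to -1.36 in female knockouts. The difference therefore shrank through the fall in heterozygotes, with no gain in knockouts. The Pou5f1 difference went from -7.73 at E12.5 to -0.81 at E15.5 (2.23 ± 0.23 per day), and Dppa3 (2.14 ± 0.21) and Sox2 (2.08 ± 0.33) moved alike. Of 14 cell cycle genes 4 rose relative to heterozygotes (9 adjusted over the list alone), with Pcna at 0.55 ± 0.08 per day, and so did 3 of 10 erythroid genes (7 adjusted over the list alone). With an estimated correlation these lists had adjusted p = 0.280 and 0.506. In males the effect became more negative for Dnmt3l (-3.04 ± 0.49 per day, and -1.97 without E12.5), Tdrd9 (-3.11 ± 0.36) and Piwil2 (-1.36 ± 0.13, and -0.57 with quantile normalization). Male heterozygotes rose by 3.02, 2.44 and 1.16 per day for these genes, which makes up most of these changes. Of 23 pan-germline genes 1 rose and 3 fell (3 and 9 adjusted over the list alone; adjusted p = 0.981 for the list with an estimated correlation), and 2 of 9 oocyte genes fell (2 adjusted over the list alone). The calls of all single genes in this paragraph ended under at least 1 alternative that kept all days.

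These slopes called 532 genes in females (306 positive, 226 negative) and 681 in males (74 and 607), on 4 residual degrees of freedom. In females 0 genes were called by limma without any 1 of the 4 days (2275 to 3184 at an unadjusted p under 0.05), 44 with no filter, 18 with array weights, 97 with no block for day and 313 with no common limit. In males the counts without E12.5, E13.5, E14.5 and E15.5 were 68, 154, 16 and 2, and 183 with quantile normalization, 132 with no filter, 261 with no block for day and 2050 with the arrays as deposited.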

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

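The tests of explanations and the counts over other splits of the samples were chosen only after the results were seen, while the tests of differences between sexes and days were planned before the data were examined.

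Erythroid genes were higher in female knockout gonads, most at E14.5 and E15.5, where the median difference of 11 erythroid progenitor genes was 3.88 and 3.99. This list was written after the data were examined and holds genes already seen among the largest increases, such as Hemgn. Its gap to hepatocyte and globin genes is therefore partly built in. The erythroid list fixed before the data were examined had medians of 2.27 and 2.66 on these days. Liver tissue carried along with the gonads stays open as the source at E14.5 and E15.5. The comparison that follows takes the ratio of erythroid to hepatocyte RNA in liver as equal on all days, which was not checked. From the first 2 to the last 2 days the knockout difference of 21 hepatocyte genes changed by -0.55 in the median over genes (-0.41 without E13.5). That of the progenitor genes changed by 2.42 (2.95). At E12.5 and E13.5 the progenitor medians were 0.93 and 1.89, near those of the hepatocyte genes, so liver as the source on these days stays open too. Hepatocyte genes were still higher in female knockouts (15 of 21 called, with medians of 1.02, 2.33, 1.08 and 1.55 by day, against 4 of 21 in males with 0.31, 1.24, 0.80 and -0.13), so some liver RNA may be present. For a difference of the knockout effect between the sexes, limma called 0 of these 21 genes (median -0.75) and 0 of the 11 progenitor genes (median -1.79). More of the blood that heterozygous gonads hold is argued against as the whole source by the 3 embryonic globin genes, whose differences at E14.5 and E15.5 had medians of 0.86 and 0.19 and reached at most 2.04 (Hbb-bh1), although 2 of the 3 were called higher and some more blood may be present. Immature blood cells of several kinds, in or beside the gonad, stay open. Megakaryocyte and granulocyte genes had a median difference of 2.13 in females and 0.57 in males. This list was also written after the data were examined. It holds genes seen among the largest increases, such as Prg2, so its median does not test the explanation. The test of the difference between the sexes called 0 of its 16 genes (median -1.50). Whether genotype or dissection brings such cells was not tested.

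More genes were called higher than lower in knockouts of both sexes. This balance depends on the scaling of the arrays, and which scaling is right was not decided: 79.1% of the calls in females and 83.1% in males were lower with the arrays as deposited, and 43.9% and 48.2% with median scaling. The loss of germ cell RNA, which raises the share of every other cell type alike, could also give small increases of all somatic genes. The medians of 6 somatic lists lay within 0.30 of each other in females and 0.35 in males, but within 0.50 and 1.26 with quantile normalization, so this stays open. Neither explanation was separated from a small real rise in somatic cells.

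Stra8 rose with day in female knockouts by 1.95 per day, a call that ended in 7 of 13 other settings with slopes from 1.44 to 2.08. The detection limit and the scaling are argued against as sources of the slope, which was 1.99 with the arrays as deposited (adjusted p = 0.0530) and 1.95 with no common limit. Germ cells like those of heterozygotes would bring all meiosis genes in the same share. At E15.5 the Stra8 difference was -3.94, and 7 of the other 23 meiosis genes lay below it by more than 2 SD, down to -9.77 for Syce3. Another 3 lay above it by more than 2 SD. The SD is that of a difference between 2 genes in 1 pair of samples, from the fit with day slopes. All these comparisons share 1 Stra8 value from 1 pair, and the heterozygous Stra8 level was at its lowest that day. Such cells are therefore argued against as the source at E15.5 only as far as 1 pair can show. Up to E14.5 such germ cells stay open, since the Stra8 difference (-9.62) was below the median of the other meiosis genes (-7.29) and so small a share would not show in most of them. Germ cells at another stage and a change of Stra8 in another cell type were not tested.

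Samples of the same day deviate together, so the real split of the 8 samples of a comparison into 4 and 4, or of the 8 pairs for the difference between the sexes, is set beside the splits that part all 4 pairs of a day as it does. These are 8 of the 35 splits, too few for a share under 0.05. In a split that swaps the groups within some pairs, real differences enter the residual spread and lower the count. No conclusion on chance is drawn from these counts. The real count and the highest other count among them were 5610 and 0 for the female knockout effect, 5686 and 4 for the male one, 145 and 0 for their difference, 3949 and 0 for sex in heterozygotes and 2991 and 0 for sex in knockouts. For the knockout effect changing with day they were 532 and 11 in females and 681 and 144 in males. The other splits part fewer pairs, and over all 35 the highest other counts were 448, 1221, 3, 2366, 0, 138 and 758 in the order above. Over all 35, only the real one (1 split) gave as many genes in all but the last of these, and 3 splits did in the last. The counts of 145 and 532 also depend on the days used: limma called 0 genes without E14.5 for the former and 0 without any 1 day for the latter (1374 and 2275 to 3184 at an unadjusted p under 0.05). Without E12.5 the former count rose.

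The following values stood apart from the other 3 of their group in 156 groups examined, where chance gives 1 in 20. In female knockouts against heterozygotes these were Rnase2a at E14.5 (7.11, the others 1.79 to 2.35) and Robo4 at E12.5 (0.52, the others 0.67 to 0.69). In males they were Egr4 at E12.5 (-5.87, the others -10.85 to -10.35) and Stra8 at E12.5 (-4.33, the others -8.35 to -8.11). Between the sexes they were Stra8 in heterozygotes at E15.5 (-1.88), and in knockouts Dnmt3l at E13.5 (-0.52), Hsd17b3 at E12.5 (7.89) and Sycp3 at E12.5 (0.44). The female knockout sample of E13.5 had 731 genes at the common limit, against 903 to 915 in the other 3.

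The knockout effect differed between the sexes for 145 genes, by the test of the difference. Among these, the male minus female effect was 4.28 for Cited1, 4.46 for M1ap, 4.78 for Majin and 4.22 for Meioc. It was -4.95 for Creg2, -1.78 for Sp5, -4.79 for Tdrd5, -5.31 for Ucma, -5.82 for Egr4 and -4.54 for Uba1y, which is Y-linked and at the limit in all 8 female samples, so that this value is the male effect alone. Egr4 was at the limit in all 4 female knockout samples, so its difference is not exact and may be smaller in size. The calls for Egr4, Cited1 and Creg2 ended in 9, 5 and 3 of 14 other settings, over which Creg2 ran from -5.50 to -2.99. The knockout effect changed with day for 532 genes in females. Per day this change was 0.61 for Ccna2, 2.14 for Dppa3, 0.93 for Gata1, 2.35 for Gdf3, 0.55 for Pcna, 2.23 for Pou5f1, 1.20 for Rhag and 2.08 for Sox2. It was -0.55 for Gli1, -1.24 for Msh4, -1.23 for Lhx8 and -2.57 for Reg2, of which Lhx8 and Reg2 were at the limit in all 4 female knockout samples, so that the value is minus the slope of the heterozygotes alone. In males it changed for 681 genes, by 1.21 for Epcam, 1.86 for Lhx1, -3.04 for Dnmt3l, -1.91 for Padi6 and -0.85 for Pax8. For Piwil2 it was -1.36, for Sly -3.14 (at the limit in 3 of 4 male knockout samples), for Tdrd1 -1.69 and for Tdrd9 -3.11.

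Probes without a single gene name were outside all comparisons. Of 4751 such probes, 173 were lower at least 2-fold in female knockouts and 142 in male knockouts, 65 of them in both.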

How the results depend on the processing

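No named gene's called value changed sign: of 3407 values under other settings 2885 kept their side of the threshold (a value called in neither could change sign), 507 kept the direction but lost the call, and 15 gained it. Named genes whose call held in every setting were 20 of 47 in female and 15 of 36 in male knockouts, 0 of 10 for the difference between the sexes, 18 of 25 and 17 of 21 for sex in heterozygotes and knockouts, 1 of 15, 2 of 14, 0 of 13 and 0 of 14 for day (female and male heterozygotes, female and male knockouts), and 0 of 12 and 0 of 9 for the knockout effect changing with day. Filters on the mean level and floors at other percentiles were not run, since values centred per probe carry no level and a common limit replaced the floor. The fit of array weights did not converge fully in 1 model. Scaling as deposited, median scaling, the stricter filter and the fit with no common limit were chosen after seeing the data. The cause was not tested for any change below, except that fewer samples leave fewer degrees of freedom.

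Without the block for day (the paired term) the counts were 1144 for female knockouts (842 at least 2-fold), 1037 for male knockouts, 41 for the difference between the sexes, and 97 and 261 for the effect changing with day in females and males. With only the 2 groups compared they were 3588 for female knockouts and 2030 for sex in heterozygotes. With no filter they were 44 for the difference between the sexes, and 44 and 132 for the effect changing with day. With array weights they were 892 for the difference between the sexes, 5444 for sex in knockouts, 799, 6515, 4966 and 5148 for day in the order above, and 18 for the effect changing with day in females. With quantile normalization they were 957 for day in female knockouts and 183 for the effect changing with day in males. With the arrays as deposited they were 2296 and 1943 for female and male knockouts, 72 for the difference, 3098 and 506 for day in female heterozygotes and male knockouts, and 2050 for the effect changing with day in males. With no common limit they were 82 for the difference and 313 for the effect changing with day in females.

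With each day left out in turn, counts ran from 1551 to 4992 for female knockouts (767 to 1541 at least 2-fold), 1568 to 5247 for male knockouts (625 to 1428), and 0 to 1123 for the difference. They ran from 1452 to 5376 for sex in heterozygotes (1192 to 2922) and from 1437 to 3502 in knockouts (1205 to 2121). For day they ran from 47 to 1289, 261 to 2821, 0 to 511 and 0 to 1126, and for the effect changing with day from 0 to 0 in females and 2 to 154 in males. Where limma called 0 genes, 1374 (difference), 1994 and 1871 (day in female and male knockouts) and 2275 to 3184 (effect changing with day) had an unadjusted p under 0.05.

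Gene lists called by camera numbered 6, 11 and 5 for the female and male knockouts and their difference, and 0, 0 and 0 with an estimated correlation, with fry at 16, 17 and 2. For sex in heterozygotes and knockouts they numbered 13 and 11, and 3 and 5 with an estimated correlation. For day they numbered 4, 8, 0 and 6, and 0 in each group with an estimated correlation, with fry at 3 and 10 in female and male knockouts. For the effect changing with day they numbered 3 and 3, and 0 and 0 with an estimated correlation, with fry at 1 in males.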

Other observations

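The genes below were grouped by tissue only after their values were seen, and no test of an explanation was run on them. Some genes of other tissues changed with day. In female knockouts the kidney and tubule genes Tinag (-2.14 ± 0.36 per day, with the samples of E14.5 and E15.5 at the limit), Pdzk1 (-2.02 ± 0.41) and Kif12 (-2.17 ± 0.32) and the kidney stroma gene Foxd1 (-1.95 ± 0.28) fell, while the mast cell protease gene Cma1 rose (2.30 ± 0.26). In male knockouts the muscle genes Myl1 (-2.40 ± 0.39 per day) and Nppa (-1.72 ± 0.40, with -0.70 under array weights, -2.60 without E15.5 and -0.37 without E12.5, the sample with its highest level, 5.52) fell, and the neutrophil genes Camp (2.51 ± 0.44), S100a9 (2.06 ± 0.51), Stfa1 (1.86 ± 0.41) and Stfa2 (2.11 ± 0.39) rose. None of these calls held with every day left out in turn. Levels of some of these genes varied widely in heterozygotes too, such as Foxd1 (-1.96 to 2.35) and Pdzk1 (-3.22 to 1.83) in females and Camp (-2.49 to 2.81) and Stfa2 (-2.12 to 2.57) in males. The tests of the knockout effect changing with day called Kif12 in females and Myl1 in males and none of the others in the sex where they are named.

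Lefty2, on the list of male germ cell genes, was present in male knockouts: its level rose by 1.35 ± 0.34 per day (0.53 without E12.5 and 0.70 with array weights, with the call lost in 7 of 13 other settings) and averaged 3.23 over the 4 samples, against 4.69 in male heterozygotes and -2.31 in female knockouts. The Y-linked gene Uba1y was higher in male than in female heterozygotes by at least 765-fold.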
